A study of Mus musculus with 4 samples.

How the data were processed

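Single-cell RNA sequencing was done on smooth muscle cells sorted for green fluorescence from the ascending aorta and aortic arch of C57BL/6J mice aged 12 weeks. Per the labels, 2 libraries came from control mice (WT) and 2 from mice with floxed Tgfbr1 and Tgfbr2 (KO). Both genotypes carried a tamoxifen-inducible Cre recombinase under the Myh11 promoter and the mT/mG reporter, which makes tdTomato before and eGFP after recombination. The labels name Chromium Next GEM 3′ chemistry v3.1, digestion of the tissue in the cold, and a gate for single, viable, GFP-positive cells.

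The deposited matrices hold UMI counts per gene and cell barcode, not normalized, made with Cell Ranger 5.0.1 per the file headers. The genome build is mm10 per the submitters' processing notes, which also name Seurat 4.0 without its role. The matrices list 32287 genes, among them eGFP and tdTomato, and 78 repeated symbols were kept apart by gene identifier. They hold 14696 barcodes: 2769 and 3565 in WT 1 and WT 2, and 4504 and 3858 in KO 1 and KO 2. The labels state fewer cells even before filtering, 2597, 3420, 4376 and 3707 in the same order, and 2151, 3000, 4031 and 3246 after it. The criteria of that filter are not given in the sources used here.

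Cells with at least 1000 UMIs, at least 500 detected genes and at most 10% mitochondrial UMIs were kept, 13468 in all, or 2429, 3265, 4252 and 3522 per library. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 nearest neighbours were used for Leiden clustering at resolution 0.5 (scanpy 1.11.5, igraph 0.11.9, seed 1). A cluster was named only from marker lists for smooth muscle and the other cell types such a sort could hold. A sub-cluster of 8 endothelial-like cells was left out of the tests. A pair of clusters of low UMI count, with 554 and 119 cells, stayed unnamed and in the tests, apart from those 8 cells. No doublet was removed for the results in the report. Scrublet's automatic threshold marked 0.947%, 0.858%, 0.235% and 0.454% of the cells of WT 1, WT 2, KO 1 and KO 2, and one alternative removed 47, 85, 145 and 99 cells with the highest scores instead.

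UMI counts were summed over the cells of each library, scaled with TMM factors, which lay between 0.99 and 1.02, and compared between KO and WT with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3). Genes passed edgeR's default expression filter, and p-values were adjusted over the 14454 tested genes by the Benjamini-Hochberg method with a threshold of 0.05. An adjusted p without another name comes from this test. CPM values are counts on the common scale of the TMM-adjusted library totals, given as mean ± SD of 2 libraries. Depth was 35255748 and 49723949 UMIs in the kept cells of the WT libraries and 59203071 and 50605349 in those of the KO libraries. At this depth the biological coefficient of variation was 7.84%, and chi-square per degree of freedom was 14.2 between the WT libraries and 16.0 between the KO libraries, so libraries of one genotype differed by more than counting error. Intervals cover counting error only.

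A family of 28 gene lists was tested with camera (limma 3.58.1) at its preset correlation of 0.01, with adjustment over the lists. The matrix lists were fibrillar and associated collagens, elastic fibre genes, basement membrane genes, proteoglycans and matricellular genes, collagen folding and crosslinking enzymes, and matrix proteases and inhibitors. The signalling lists were TGF-beta target genes, TGF-beta ligands and receptors with SMADs, BMP target genes, secreted growth factors, feedback genes of mTOR, MAPK and AKT, and Notch and Hippo genes. The smooth muscle lists were contractile genes, integrins and focal adhesion genes, vasoactive receptors and ion channels, modulated smooth muscle genes, chondrogenic and osteogenic genes, and regional transcription factors. The remaining lists were inflammatory genes, interferon-stimulated genes, immediate early and dissociation stress genes, endoplasmic reticulum stress genes, p53 targets and senescence, cell cycle, glycolysis, oxidative phosphorylation, cholesterol and lipid handling, and lysosome and autophagy. Some genes stand in several lists, and the 28 lists hold 687 different genes. Sex-linked genes were described outside this family. Each list was also tested with camera under an estimated correlation and with fry, which asks whether its members move, on balance, in one direction.

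Genes were named by a rule: Tgfbr1, Tgfbr2, Myh11 and the sex-linked genes, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 20 CPM and no overlap between genotypes (gene models without a name left out), the 3 members of each list with the smallest p, and the 5 genes with the smallest p in the test of subclusters. Some genes that this rule names are not reported here. Other genes in the text were picked after their values were seen. Gene positions are those of GENCODE M21 on GRCm38, the assembly also called mm10.

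Subclusters of smooth muscle cells were made after removing 5801 genes with a genotype adjusted p under 0.2, with each remaining gene centred per library. The genotype effect was tested in each subcluster with at least 100 cells in every library, and its difference between the largest pair with an interaction term and the library as a block. A matrix score per cell summed the CPM of the collagen and elastic fibre lists, 39 genes, after thinning each cell to 5000 UMIs. Cells below that depth, 197, 162, 150 and 169 in WT 1, WT 2, KO 1 and KO 2, were left out of it. Shares of cells and median scores of the libraries were compared by exact two-sided permutation tests, which cannot go below p = 0.333 with 2 libraries against 2.

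The gene test was tested on simulated counts made from the means and depths of these libraries, with 200 genes changed, in 8 simulations for each of 2 settings of the spread. With each gene's own spread, 86.9% of 1.5-fold, 99.3% of 2-fold and 100% of 4-fold changes were called among 14264 to 14305 tested genes. Unchanged genes made up 11.7% of the calls on average, from 6.8% to 14.8%, or 25.4 genes per simulation. The first limit set for this share was 10%, and 7 of these 8 simulations exceeded it. With the spread taken from the trend the mean was 4% and none of the 8 exceeded 10%. The criterion was afterwards changed to the recovery of 2-fold changes and the share of unchanged genes with an unadjusted p under 0.05. That share was 4.52% to 5.38% with own spread and 4.58% to 5.2% with the trend. A limit on the mean false share was kept only for the spread taken from the trend, and none was set for each gene's own spread. The false share reached 14.8% in simulations with own spread. The simulations changed 200 genes, while 2926 were called in the data, so the simulated false share cannot be carried over. The false share among the called genes of the data stays unknown. The interaction test recovered 78% of 1.5-fold and 97.8% of 2-fold differences in 4 simulations, with a mean false share of 3.52%.

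Groups, tests, gene lists, markers, the naming rule and most alternatives were fixed before the data were examined. The alternatives covered DESeq2 1.42.0 and limma-voom, other scaling, other filters on genes and cells, doublet scores, equal cell numbers, thinning, other clustering, a replicate block and leaving out each library in turn. When a library is left out, the lone library of its genotype is assumed to vary like the others. Alternatives chosen after seeing the data left out cells with blood or vessel lining markers, the pair of low-UMI clusters, tdTomato-positive cells, or genes near the floxed loci, and compared the subcluster with the highest Rgs5. The numerical work also used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.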

Results

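The 4 libraries profiled GFP-positive aortic smooth muscle cells, 2 from control mice (WT) and 2 from mice in which Cre under the Myh11 promoter was to delete both type I and type II TGF-beta receptors (KO). The series title places this comparison in a question about TGF-beta, matrix production and dissection of the aorta under hypertension, and asks what smooth muscle cells express with and without these receptors. The libraries held 35715682 (WT 1), 50093465 (WT 2), 59498336 (KO 1) and 51107663 (KO 2) UMIs, with a median of 14768, 15383, 13898 and 14399 UMIs and 3897, 3992, 3762 and 3844 genes per kept cell. Median mitochondrial shares were 4.62%, 3.86%, 3.76% and 3.83%. The labels speak of individual aortic segments but not of how many mice each library holds. P-values of the gene test therefore measure the spread between these samples. Tamoxifen was given for 5 days either at 4 or at 11 weeks of age, and the labels do not say which library had which course, nor whether the course differed by genotype, so its effect cannot be separated from that of the genotype. The labels give no batch or date.

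The transcripts of the targeted receptors were present in every library. Tgfbr1 stood at 80.9 and 82.4 CPM in WT 1 and WT 2 and at 73.3 and 76.1 CPM in KO 1 and KO 2 (log2 difference −0.13, SE 0.06, adjusted p = 0.204). Tgfbr2 stood at 51.7 and 45.1 CPM in WT and 46.4 and 47.2 CPM in KO (−0.05, SE 0.08, adjusted p = 0.730). The labels do not name the floxed exons, and 3′ tags that lie outside the deleted part check nothing about recombination, so these values neither test nor question the genotype labels. On GRCm38, Tgfbr1 covers chromosome 4 from 47353222 to 47414931 and Tgfbr2 chromosome 9 from 116084293 to 116175360. Myh11, the smooth muscle myosin heavy chain whose promoter drives Cre, rose from 5314 ± 148 to 7113 ± 120 CPM (log2 0.42, SE 0.05, adjusted p = 0.000761). The Y-linked genes Ddx3y (105.8, 117.1, 110.5 and 110.7 CPM in WT 1, WT 2, KO 1 and KO 2), Eif2s3y (64.5, 68.4, 65.4 and 68.2 CPM) and Uty (20.9, 20.04, 17.4 and 19.2 CPM) were counted in all 4 libraries, and Xist was at 0.430, 0.325, 0.354 and 0.486 CPM. Their differences had adjusted p-values of 0.926, 0.9499, 0.220 and 0.790. Kdm5d, also Y-linked, stood at 12.1, 11.9, 14.5 and 15.3 CPM and passed the test (log2 0.31, SE 0.09, adjusted p = 0.0387). It lost the call with DESeq2 (adjusted p = 0.0977) and without each library in turn, where the adjusted p ran from 0.070 without KO 1 to 0.144 without KO 2, with 0.111 without WT 1 and 0.128 without WT 2.

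Transcripts of elastin and several other matrix proteins fell steeply in KO smooth muscle cells. Elastin (Eln), the core of the elastic fibre, fell from 2781 ± 15.9 to 279 ± 66.6 CPM (log2 −3.31, SE 0.14, adjusted p = 5.4e-06). Mfap4, a glycoprotein of elastic microfibrils, fell by 4.22 (SE 0.07), Aspn, a small leucine-rich proteoglycan, by 3.92 (SE 0.13) on the log2 scale, and Ccn5, a matricellular protein, had a log2 change of −3.50 (SE 0.12). Pmepa1, a feedback inhibitor of TGF-beta signalling, fell from 1193 ± 46.1 to 149 ± 4.87 CPM. Nupr1, a stress-induced chromatin protein, fell by 3.49 (SE 0.06) and the NADPH oxidase Nox4 by 2.59 (SE 0.09). The proprotein convertase Pcsk5, the immediate early gene Fos and the myosin kinase gene Mylk4 had log2 changes of −2.97, −2.63 and −2.60. Adjusted p-values of these falls lay between 3.6e-08 (Mfap4) and 5.4e-06 (Eln).

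The named genes with the largest falls were the unassigned transcript AA465934 (88.2 ± 2.43 to 0.994 ± 0.024 CPM, log2 −6.47, SE 0.10) and Col15a1, collagen XV of the basement membrane zone (289 ± 12.8 to 4.56 ± 0.53 CPM, −5.98, SE 0.10), each with an adjusted p of 3.6e-08. AA465934 is annotated as a processed transcript on chromosome 11 from 83291699 to 83294632. Col15a1, on chromosome 4 from 47208161 to 47313167, lies 40.1 kb from the floxed gene Tgfbr1. Eln lies on chromosome 5 from 134702593 to 134747323 and Mfap4 on chromosome 11 from 61485431 to 61488900, neither on the chromosome of a floxed gene. UMI counts cover whole gene models and are not split by exon or UTR.

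Among genes with a mean of at least 20 CPM the rises were smaller and spread over different functions. Itih4, a secreted protein of the inter-alpha-trypsin inhibitor family on chromosome 14 from 30886476 to 30902353, rose from 161 ± 30.6 to 914 ± 114 CPM (log2 2.51, SE 0.14, adjusted p = 1.8e-05). Clec2d, a C-type lectin, and Nrgn, a calmodulin-binding protein, both rose by 1.87 on the log2 scale (SE 0.14 and 0.12). The actin-binding protein gene Ablim1 and Ddit4l, an inhibitor of mTOR signalling, rose by 1.82 each, and Cidea, a protein of lipid droplets, by 1.59. Ifitm3, an interferon-induced membrane protein, rose from 173 ± 3.03 to 504 ± 107 CPM. Timp4, an inhibitor of metalloproteinases, and Tnnt2, cardiac troponin T, rose by 1.51 and 1.34. Plvap, a protein of endothelial diaphragms, rose by 1.51, while the 13 endothelial markers summed to 160 and 164 CPM in the WT and 167 and 181 CPM in the KO libraries. Fabp4 made up most of each sum (130 and 133 CPM in WT, 136 and 153 CPM in KO), while Pecam1 fell (log2 −0.65, adjusted p = 0.00555) and Vwf rose (1.17, adjusted p = 0.0211, under 2 CPM in every library). Dctn3, a dynactin subunit on the chromosome of Tgfbr1 (41714798 to 41723170), rose by 1.33, and the homeobox gene Prrx2 by 1.24 (SE 0.25, adjusted p = 0.00954, the highest among these 12).

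**Figure D1:**
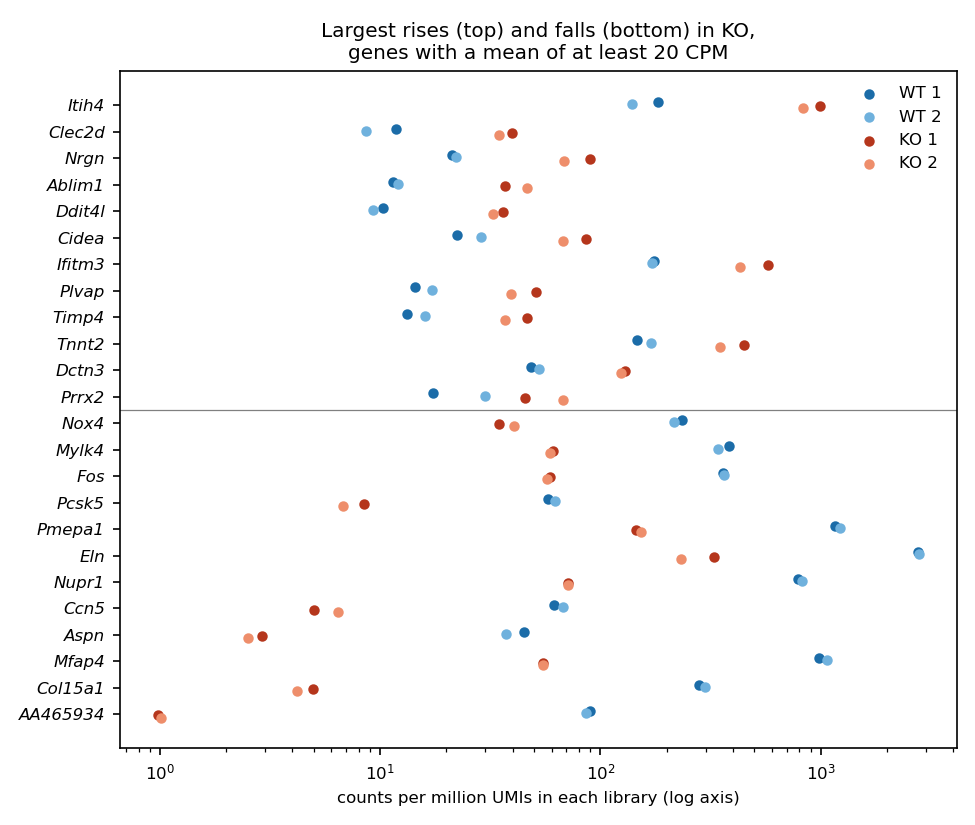
CPM (log axis) of the 12 largest rises (upper part) and the 12 largest falls (lower part) among called, named genes with a mean of at least 20 CPM and no overlap between genotypes, with a point for each of the 4 libraries. For every gene the 2 KO libraries lie beyond both WT libraries, from 0.994 CPM for AA465934 in KO to 2781 CPM for Eln in WT on average.

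Among 14454 tested genes, 1301 were higher and 1625 lower in KO by edgeR's quasi-likelihood test, and 411 of the former and 392 of the latter changed at least 2-fold. In 100% of the called genes both KO libraries lay beyond both WT libraries, against 63.4% of all tested genes and 33.3% by chance. Without WT 1 the counts were 779 higher and 1035 lower, a fall of more than 1.5 times. After TMM scaling the median log2 change of the tested genes was −0.01.

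TGF-beta target genes fell as a group. Of 18 measured members 13 fell, 1 rose and 4 did not pass, or 14 lower and 2 higher when adjusted over the list alone, with a median log2 change of −1.17 (camera adjusted p = 2.5e-23). Besides Pmepa1 and Nox4, the SMAD inhibitor gene Skil fell by 1.63 (SE 0.07). Ccn2, a matricellular growth factor, had a change of −2.56. The rise of Tgfbi rested on few UMIs, 1 and 1 in WT against 24 and 16 in KO. With an estimated correlation the list was not called (adjusted p = 0.118). None of the 28 lists was called by camera with an estimated correlation, although 7 had an unadjusted p under 0.05 there. The preset correlation called 18 and fry called 12. With only 4 libraries the estimated correlation leaves little power, so a list not called there is not shown to be unchanged. The preset p-values rest on an assumed correlation and on the spread between genes, not on the spread between libraries alone. Ranges in brackets give each list's adjusted p over its 23 alternatives, here 4.48e-32 to 0.118.

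The collagen, elastic fibre and basement membrane lists fell, with exceptions among their members. Of 15 collagen genes 9 fell, 1 rose and 5 did not pass (10 lower and 2 higher adjusted over the list alone, median −0.55, camera adjusted p = 4.3e-20, adjusted p = 0.118 with an estimated correlation, range 3.34e-33 to 0.118). Col3a1, a fibrillar collagen of vessel walls, fell from 1307 ± 9.40 to 423 ± 14.3 CPM and Col5a2 by 1.27. Of 20 elastic fibre genes 12 fell, 1 rose and 7 did not pass (12 and 1 adjusted over the list alone, median −0.39, camera adjusted p = 2.4e-18, adjusted p = 0.147 with an estimated correlation, range 1.06e-26 to 0.147). Besides Eln and Mfap4, the elastic fibre assembly gene Fbln5 fell by 2.45 (SE 0.08) and the crosslinking enzyme gene Lox by 2.16 (SE 0.08). The member that rose was Efemp1 (1.58), a fibulin. Of 17 basement membrane genes 9 fell and 8 did not pass (10 lower and 2 higher adjusted over the list alone, median −0.40, camera adjusted p = 6.3e-06, adjusted p = 0.174 with an estimated correlation, range 2.60e-08 to 0.174). Sparc, which binds collagen, fell by 1.37, nephronectin (Npnt) by 0.89 and Col4a2 by 0.76.

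Proteoglycans and matricellular genes fell as a list, with several steep rises among them. Of 22 members 13 fell, 5 rose and 4 did not pass (13 and 6 adjusted over the list alone, median −0.69, mean −0.23, camera adjusted p = 9.8e-15, adjusted p = 0.118 with an estimated correlation, range 2.54e-24 to 0.118). Aspn and osteomodulin (Omd) fell by 3.92 and 2.40 and Ccn1 by 1.71. Lumican (Lum), a small leucine-rich proteoglycan, rose from 1.05 ± 0.22 to 14.5 ± 5.27 CPM, and Prg4 rose on low counts of 2 and 1 in WT and 21 and 43 in KO. Of 17 genes for collagen folding and crosslinking 13 fell, 2 rose and 2 did not pass, with the same counts adjusted over the list alone (median −0.50, camera adjusted p = 8.1e-07, adjusted p = 0.170 with an estimated correlation, range 8.89e-09 to 0.170). The lysyl hydroxylase gene Plod2 fell by 1.59 and the procollagen peptidase gene Adamts2 by 0.61, while Pcolce2, an enhancer of procollagen cleavage, rose by 1.05. Matrix proteases and inhibitors had no common direction, with 7 of 25 higher, 7 lower and 11 not passing (8 and 9 adjusted over the list alone, camera adjusted p = 0.805). There the protease gene Htra1 fell by 1.20, cathepsin L (Ctsl) fell by 0.94, and the metalloproteinase gene Mmp3 rose from 0.791 ± 0.35 to 7.23 ± 1.37 CPM.

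Nearly all KO cells lay below the median WT cell in their matrix transcripts. The summed collagen and elastic fibre transcripts per cell had library medians of 11150 ± 70.7 CPM in WT and 4500 ± 141 CPM in KO (SD, n = 2), a difference of −6650 CPM, with KO at 40.4% of the WT level. With 2 libraries against 2 the exact permutation test gave p = 0.333, its smallest possible value. Of the KO cells, 23 of 4097 in KO 1 (0.561%) and 26 of 3350 in KO 2 (0.776%) exceeded the median WT cell. Without thinning the difference was −6624 CPM and the shares were 0.777% and 1.31%.

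**Figure D2:**
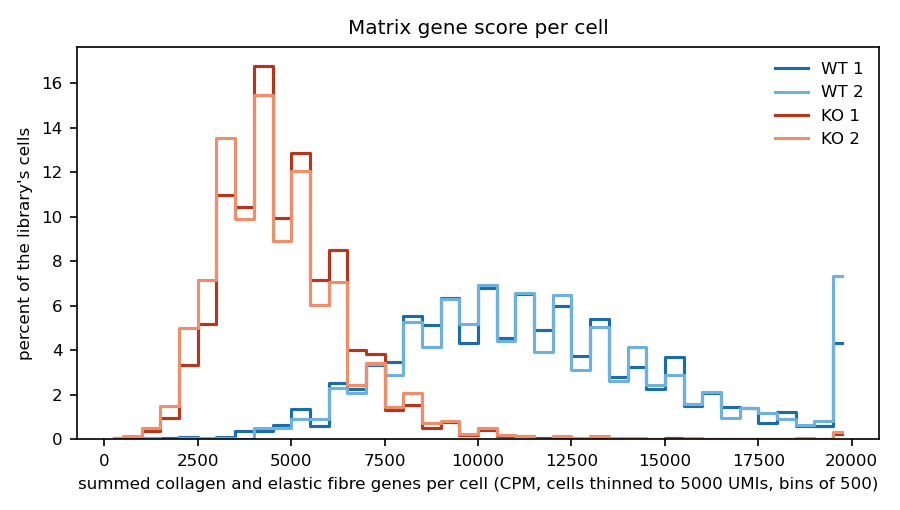
Percent of each library's cells by their summed collagen and elastic fibre transcripts (CPM per cell, cells thinned to 5000 UMIs, bins of 500), with a line for each of the 4 libraries. The last bin starts at 19500 and holds all cells above it, and the KO lines centre on medians of 4600 and 4400 against 11100 and 11200 in WT.

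Genes of the contractile apparatus rose slightly as a list, with members on both sides. Of 33 members 13 rose, 6 fell and 14 did not pass (16 and 6 adjusted over the list alone, median 0.16, camera adjusted p = 0.0160, adjusted p = 0.255 with an estimated correlation, range 0.00285 to 0.255). Mustn1, a small nuclear protein of muscle, rose from 497 ± 23.7 to 1038 ± 97.3 CPM, and tropomyosin Tpm2 and desmin (Des) rose by 0.67 and 0.69. Smooth muscle actin (Acta2, log2 0.05, adjusted p = 0.534) and transgelin (Tagln, 0.05, adjusted p = 0.600) did not pass. Susd5 and the LIM domain gene Pdlim7 fell by 1.01 and 0.84. Of 32 integrins and focal adhesion genes 14 fell, 2 rose and 16 did not pass (16 and 3 adjusted over the list alone, median −0.17, camera adjusted p = 0.000521, adjusted p = 0.255 with an estimated correlation, range 2.43e-05 to 0.255). The matrix receptors Itgb5 and Itgb3 fell by 1.02 and 0.94 and the actin crosslinker Actn1 by 0.68.

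Markers of modulated smooth muscle cells, a less contractile state, rose as a list, but few members carried it. Of 16 members 6 rose, 2 fell and 8 did not pass (10 and 2 adjusted over the list alone, median 0.45, camera adjusted p = 0.00111, adjusted p = 0.228 with an estimated correlation, range 4.97e-06 to 0.585). Lum rose by 3.81 and Mmp3 by 3.14, both also matrix genes, while fibronectin (Fn1) fell by 0.79. The call was lost and the median was −0.08 among genes with a mean of at least 20 CPM, and without KO 2 the median was 0.25. Of 19 chondrogenic and osteogenic genes 6 fell, 2 rose and 11 did not pass, with the same counts adjusted over the list alone (median −0.08, camera adjusted p = 0.00483, adjusted p = 0.391 with an estimated correlation, range 1.72e-08 to 0.391). The calcification inhibitor Mgp fell from 6023 ± 72.8 to 2092 ± 178 CPM, aggrecan (Acan) fell by 1.67 and Enpp1, which makes pyrophosphate, by 0.87. This list lost its call without WT 1 (median −0.10, adjusted p = 0.102), without KO 1 (−0.01, 0.0898), with limma-voom and with fry, and its median was −0.14 without WT 2 and −0.38 without KO 2.

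Genes that respond to interferon rose as a list. Of 26 members 18 rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone (median 1.13, camera adjusted p = 1.4e-08, adjusted p = 0.423 with an estimated correlation, range 3.55e-49 to 0.423). Ifi27l2a rose from 1.98 ± 0.28 to 36.6 ± 21.4 CPM, the immunoproteasome subunit Psmb8 by 2.25 and the guanylate-binding protein gene Gbp2 by 0.84. Cells with at least 5 UMIs of Isg15, Ifit1, Ifit3, Ifit3b and Rsad2 together made up 0.124% and 0.061% of WT and 3.63% and 0.767% of KO cells, and held 16.3% and 3.1% of the UMIs of these 5 genes in WT 1 and WT 2 and 74.6% and 30.2% in KO 1 and KO 2. Ifit3 and Ifit3b are near-identical copies, so the split of UMIs between them is uncertain. Without KO 1 the median was 0.61, and the call was lost with fry and among genes with a mean of at least 20 CPM. The 15 macrophage markers summed to 2.30, 4.73, 17.6 and 3.12 CPM in WT 1, WT 2, KO 1 and KO 2. A sub-cluster of 88 cells led by C1qa and Ifi27l2a, with 3, 2, 46 and 37 cells in the same order, carried smooth muscle markers at 64908 CPM. All tested cells of these libraries held 1, 0, 167 and 1 UMIs of C1qa, so the 37 KO 2 cells held at most 1. Inflammatory genes rose as a list of 16, with 6 higher, 3 lower and 7 not passing, the same adjusted over the list alone (median 0.18, camera adjusted p = 0.0128, adjusted p = 0.255 with an estimated correlation, range 0.000627 to 0.255). The chemokine genes Cxcl12 and Cx3cl1 rose by 0.97 and 2.25 and the complement gene C4b by 2.49. That call was lost with limma-voom, with fry and among genes of at least 20 CPM, and the list median was 0.40 without WT 1, 0.67 without WT 2 and 0.11 without KO 1.

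Stress programmes moved apart. Of 21 endoplasmic reticulum stress genes 16 fell and 5 did not pass (18 lower and 1 higher adjusted over the list alone, median −0.48, camera adjusted p = 5.1e-07, adjusted p = 0.254 with an estimated correlation, range 8.71e-10 to 0.254), among them the chaperone Hspa5 (−0.76), the transcription factor Xbp1 (−0.78) and Hyou1 (−0.59). Of 32 immediate early and dissociation stress genes 11 fell, 4 rose and 17 did not pass (13 and 5 adjusted over the list alone, median −0.15, camera adjusted p = 0.000141, adjusted p = 0.174 with an estimated correlation, range 1.45e-07 to 0.174). Besides Fos, the transcription factor gene Klf2 fell by 1.90 and the phosphatase gene Dusp1 by 1.52. This call was lost with limma-voom, and the median was −0.33 without WT 1 and 0.01 without WT 2. Of 15 p53 target and senescence genes 8 rose, 2 fell and 5 did not pass (9 and 3 adjusted over the list alone, median 0.31, camera adjusted p = 0.00318, adjusted p = 0.371 with an estimated correlation, range 0.000632 to 0.371, call lost with fry). The cell cycle inhibitor Cdkn1a rose from 67.7 ± 1.17 to 126 ± 12.8 CPM, the stress cytokine Gdf15 by 1.38 and Trp53inp1 by 0.78.

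Metabolic lists differed in size and direction. Of 26 cholesterol and lipid genes 18 fell, 5 rose and 3 did not pass (19 and 5 adjusted over the list alone, median −0.56, camera adjusted p = 0.000534, adjusted p = 0.504 with an estimated correlation, range 1.26e-11 to 0.504, call lost with fry). The desaturase gene Scd1 was among those that rose (log2 1.11). Oxidative phosphorylation genes rose slightly as a list, although 33 of 38 did not pass singly and 5 rose, the same adjusted over the list alone (median 0.12, camera adjusted p = 0.00305, adjusted p = 0.648 with an estimated correlation, range 9.38e-06 to 0.648, call lost with fry). The mitochondrial coactivator gene Ppargc1a rose by 0.90, and the respiratory chain subunits Cox8a and Ndufb8 by 0.33 and 0.31, of which Ndufb8 lost its call without WT 1 (adjusted p = 0.0643) and without WT 2 (0.0529). Glycolysis genes were not called as a list (4 of 21 higher, 2 lower, 15 not passing, 5 and 3 adjusted over the list alone, camera adjusted p = 0.628), with Pfkfb3 at −0.76, Gapdh at 0.29 and Pfkm at −0.33. Gapdh lost its call without WT 1 (0.0572), WT 2 (0.0935) or KO 1 (0.0683), and Pfkm without WT 2 (0.145), KO 1 (0.0725) or KO 2 (0.0520). Lysosome and autophagy genes were not called by camera (3 of 28 higher, 5 lower, 20 not passing, 4 and 7 adjusted over the list alone, adjusted p = 0.114) but were by fry (0.0236) and by camera without a count filter (0.0478), and prosaposin (Psap) fell by 0.54.

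Among signalling lists, Notch and Hippo genes fell, with 8 of 19 lower, none higher and 11 not passing (12 lower and 2 higher adjusted over the list alone, median −0.32, camera adjusted p = 0.000123, adjusted p = 0.329 with an estimated correlation, range 8.59e-08 to 0.329, call lost with fry). The Notch effectors Heyl and Hes1 fell by 1.89 and 1.77, and without WT 1 the list median was −0.21. TGF-beta ligands, latent binding proteins, receptors and SMADs split evenly, 6 of 24 higher, 6 lower and 12 not passing (7 and 8 adjusted over the list alone, camera adjusted p = 0.502). There the latent binding proteins Ltbp3 and Ltbp4 fell by 1.46 and 0.65, and thrombospondin Thbs1, an activator of latent TGF-beta, rose from 3.69 ± 0.24 to 15.2 ± 0.09 CPM. Of 10 BMP target genes 1 was higher and 9 did not pass, and 0 were called adjusted over the list alone by edgeR (camera adjusted p = 0.941), with median 0.00 and mean −0.04. That gene, Id4 (0.36, adjusted p = 0.0441), lost its call without WT 1 (0.0840), WT 2 (0.149) or KO 1 (0.162), and Id1 (−0.28, adjusted p = 0.0666) and Bambi (−0.34, 0.130) passed without KO 1 (0.00892) and without KO 2 (0.00579), respectively. Id1 also passed with DESeq2 (0.0318), and both passed without a count filter and with the replicate number as a block.

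No common direction was called by the main test for the remaining lists. Secreted growth factors had 10 of 35 higher, 10 lower and 15 not passing (14 and 10 adjusted over the list alone, camera adjusted p = 0.502), with the IGF-binding proteins Igfbp4 at 1.20 and Igfbp2 at −1.66 and the Wnt pathway gene Dkk3 at −0.72. Among genes with a mean of at least 20 CPM this list was called lower, with a median of −0.52 against 0.16 (camera adjusted p = 0.0146). Vasoactive receptors and ion channels had 7 of 25 higher, 6 lower and 12 not passing (7 and 7 adjusted over the list alone, camera adjusted p = 0.662, median −0.03, mean 0.16). Angiotensin-converting enzyme (Ace) fell by 1.58, and the adrenergic receptor gene Adra1b and the potassium channel gene Kcnj8 rose by 2.24 and 0.94. Feedback genes of mTOR, MAPK and AKT had 5 of 21 higher, 1 lower and 15 not passing (6 and 1 adjusted over the list alone, camera adjusted p = 0.346, median −0.01, mean 0.13), with Etv5 and Deptor at 1.34 each and Spry1 at −0.83. Cell cycle genes had 4 of 25 higher, 1 lower and 20 not passing (5 and 2 adjusted over the list alone, camera adjusted p = 0.502), with Cenpa at 2.35, Mcm6 at −0.49 and Mcm3 at 0.51, which lost its call with DESeq2 and without each library in turn (adjusted p from 0.0562 without KO 2 to 0.101 without KO 1, with 0.0758 without WT 1 and 0.0788 without WT 2). Regional transcription factors had 5 of 30 higher, 3 lower and 22 not passing (7 and 5 adjusted over the list alone, camera adjusted p = 0.0747), with Hand2, Meis2 and Foxf1 at 0.55, 0.41 and 0.82, and this list was called in 6 of its 23 alternatives, among them without WT 1 (0.0131) and without KO 2 (0.0485).

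**Figure D3:**
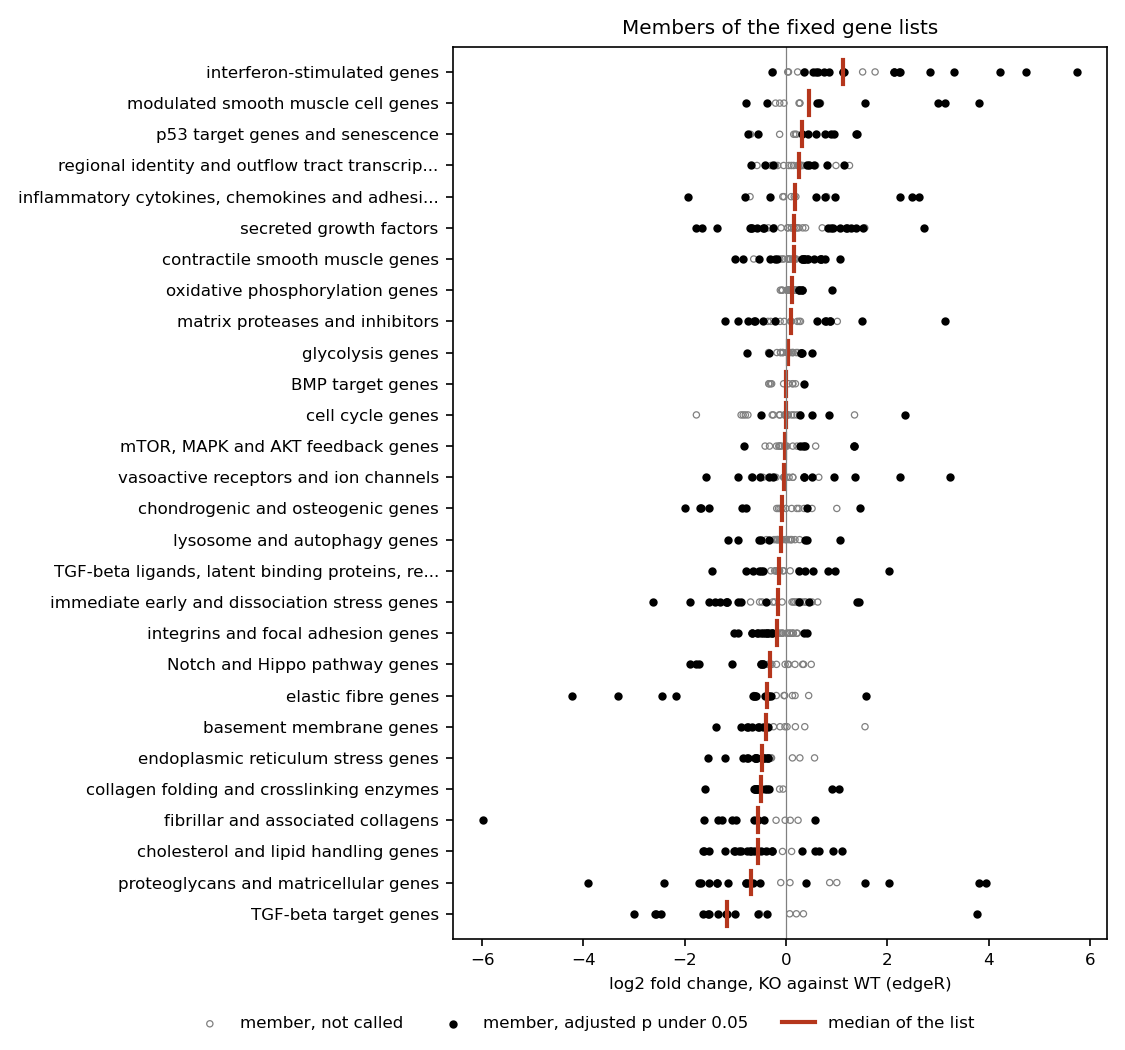
Log2 fold change of KO against WT (x axis, edgeR) for each measured member of the 28 gene lists, ordered by list median (bar), with filled points for members with an adjusted p under 0.05. Medians run from −1.17 for TGF-beta target genes to 1.13 for interferon-stimulated genes, and most lists hold called members on both sides of 0.

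Genes were called between the genotypes in each of the 5 tested subclusters of smooth muscle cells. In the 3 larger subclusters, of 3488, 3350 and 4583 cells, 851, 951 and 1145 genes rose and 1119, 1167 and 1366 fell. Of the genes called over all cells, which include these cells, 1785 of 2672, 1875 of 2686 and 2232 of 2814 measured there were called in the same direction. In a subcluster of low UMI count (720 cells) and in one with high Rgs5, a gene of pericytes and some arterial smooth muscle (1103 cells), 134 and 415 genes rose and 216 and 632 fell, and 334 of 1716 and 816 of 2409 of the calls over all cells were made there too. A test of the difference of the genotype effect between the 2 largest subclusters, led by Dcn and by Lgals1, called 10 of 13158 genes, with 665 at an unadjusted p under 0.05. Without KO 1 it called 1 gene and without WT 2 it called 16. Nupr1, Olfr655 and Col3a1 were among the 5 genes with the smallest p.

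Few cells were named as another type than smooth muscle. The sub-cluster of 88 cells led by C1qa, with 6 macrophage markers among its 10 leading genes, carried smooth muscle markers and stayed in the tests, and cells with at least 3 macrophage markers numbered 1, 1, 3 and 0 in WT 1, WT 2, KO 1 and KO 2. The 8 endothelial-like cells made up 0 of 2429 and 0 of 3265 WT cells, which allows shares of up to 0.123% and 0.0919% by a limit of 3 counts (Clopper-Pearson upper bounds 0.152% and 0.113%), and 0.118% and 0.0852% of KO cells (exact Clopper-Pearson 95% intervals 0.0382% to 0.274% and 0.0176% to 0.249%). The mean of 0.101 ± 0.023% in KO against 0 in WT had an exact permutation p of 0.333, the smallest possible, and the GFP gate sets these shares. At Leiden resolution 0.3 and with the stricter cell filter no such cluster was found in any library.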

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

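All tests of an explanation in this part were chosen only after the result was seen, as was the comparison of the subcluster with the highest Rgs5.

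The genotype effect differed between the 2 largest smooth muscle subclusters for 10 genes by an edgeR interaction term, 3 with a higher and 7 with a lower log2 change in the subcluster led by Lgals1. For Nupr1 the difference was −0.34 (SE 0.06, adjusted p = 0.00565), for Olfr655 −2.72 and for Col3a1 −0.26 (adjusted p = 0.00755). Olfr655 stayed under 10 CPM in every library of both subclusters. Without KO 1 the count was 1 and without WT 2 it was 16. In the subcluster with the highest Rgs5 the effect differed from that in the other tested subclusters for 288 of 13994 genes.

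The tdTomato reporter, which no planned comparison uses, was detected in 2.71% of KO 1 and 1.65% of KO 2 cells. In WT 1 and WT 2 it was detected in 0.041% and 0.061% of cells. Endothelial markers, from cells that keep tdTomato, were 1.07 times as high in KO as in WT libraries. Fabp4 made up most of this sum, so the ratio cannot show how large an endothelial contribution is. Vwf (0.82 and 0.54 CPM in WT, 1.66 and 1.42 CPM in KO) and Ptprb (0.62 and 0.90 CPM, 1.39 and 1.42 CPM) rose, while Pecam1 fell (14.2 and 17.5 CPM, 10.3 and 10.3 CPM). An endothelial contribution of unknown size stays open. Droplets with a second cell are argued against by the UMI count, as cells with at least 3 tdTomato UMIs had 1.11 times the median of tdTomato-negative KO cells. In those cells the median eGFP level was 50.7% and 49.5% of that of tdTomato-negative cells in KO 1 and KO 2, which may reflect 1 of 2 reporter copies left unrecombined. Median eGFP of tdTomato-negative cells itself differed by genotype. It was 5405 and 5566 CPM in the WT and 7729 and 7477 CPM in the KO libraries. The number of reporter copies per mouse is not given in the labels, so whether it differed between the genotypes is unknown. The reading of 1 copy left unrecombined stays a hypothesis, and a difference in tamoxifen course stays open too.

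A set of 23 KO cells, 13 in KO 1 and 10 in KO 2, lay in the 2 clusters made up of over 95% WT cells. They held Eln at 257%, Fbln5 at 253%, Lox at 202%, Col3a1 at 160% and Mfap4 at 70.6% of the level of WT cells there. The clustering kept genes that differ between genotypes, and Mfap4 and Eln are among the leading genes of the larger cluster. High matrix transcripts may thus be how these cells were picked and are no independent result. Carry-over from a WT library is argued against by AA465934, with 0 UMIs where the WT level would give 38.9 (upper 95% bound 9.48%). Of these cells 23.1% in KO 1 and 40% in KO 2 were tdTomato-positive, 8.72 and 26.0 times the share of the other KO cells (Fisher's exact test over cells, which are not replicates, p = 0.00454 and 1.3e-05). The clustering did not leave out eGFP and tdTomato. The reporters may thus have helped to pick these cells, and the ratios are no independent result either. Incomplete recombination of the receptor genes stays a candidate explanation that these ratios cannot decide. An earlier set of 95 KO cells was picked by a classifier that left out eGFP and tdTomato, and it gave tdTomato ratios of 4.62 and 9.77. That set was replaced after its values were seen, because 76 of its cells lay in KO clusters and Mfap4 reached only 38.7% of WT.

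Within 10 Mb of Tgfbr1, 17 of 133 tested genes (12.8%) were called with a change of at least 2-fold, against 5.55% of all tested genes. Of the windows around each tested gene, 2.7% reached as high a share. These windows overlap and include those of this region, so their share is only a rough guide. Among the 17 were several unnamed gene models of low CPM. DNA of another strain carried beside the floxed allele may contribute. Near Tgfbr2 the share was 5.12%, reached by 49.3% of windows. In the 23 KO cells Col15a1 was at 9.59% of the WT level (95% interval 5.58% to 15.4%). Its 17 UMIs compare with 1.8 at the level of the other KO cells and 177.3 at the WT level. The share met the bound set against loss of the receptors in the cell itself as its whole cause. That bound was wrong to rely on, because whether these cells kept their receptors was not measured. Fos, on another chromosome than both receptor genes, was at 2.69%. Its 3 UMIs lay below the 24.2 at the level of the other KO cells and the 111.5 at the WT level. Fos therefore cannot show whether these cells resemble the other KO cells. Receptor loss and the tissue around the cells both stay open. A search for the 2 Mb window with the most falls of at least 2-fold led to chromosome 2. Its count was thus picked as the highest, and it was not compared with other windows. There 16 of 19 tested genes fell at least 2-fold, the falling ones lying between 176798612 and 178414472. Of the 16, 14 were under 0.3 CPM in both KO libraries. Of these, 1 UMI stood against 21.1 at the WT level (4.74%, upper bound 26.4%), so with so few UMIs it stays open whether loss of the receptors in the cell changed this block, which lies on another chromosome than both receptor genes. Many of its genes belong to a multigene family, so their counts are uncertain, and shared reads were not tested. In the earlier set of 95 cells Col15a1 was at 7.18%, against 1.53% in the other KO cells. All 16 falling genes of the block were at 9.47% there (4.09% to 18.7%), against 8.32% in the other KO cells.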

How the results depend on the processing

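The tests without cells bearing blood or vessel lining markers, low-UMI clusters, tdTomato-positive cells or genes near the receptor genes, and those of the subcluster with the highest Rgs5, were chosen only after the result was seen. None of the 2926 called genes that could be tested changed sign in any of the 21 refits of the gene test. In 100% of them both KO libraries lay beyond both WT libraries, so leaving out a library could hardly turn a sign. The other refits reuse counts of the same libraries, so the lack of sign changes is no measure of stability. Of the calls that could be tested, 2401 of 2926 were kept with DESeq2, 2801 of 2926 with limma-voom and 2028 of 2775 after thinning. Of the named genes, 92 of 104 kept their direction and side of the threshold in all 21 refits. Among counts and other summary values 81 alternatives stayed close and 11 moved, and among single genes and lists 2757 stayed the same, 69 lost a call, 15 gained one and 25 reversed. The numbers of genes higher in KO smooth muscle cells and of genes lower in KO smooth muscle cells were 1129 and 1384 with DESeq2, 1244 and 1590 with limma-voom, 1535 and 1446 with library totals and 1931 and 2099 without a count filter. They were 1296 and 1616 without cells bearing those markers, 1292 and 1624 without the low-UMI clusters, 1316 and 1636 without tdTomato-positive cells, and 1251 and 1569 without genes near the receptor genes and the chromosome 2 block. With the replicate number as a block the counts were 1531 and 1802 with 19 lists, but libraries of one number did not deviate together (correlation −0.0049 across 5743 genes, which are not independent replicates).

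With a mean of at least 20 CPM, 5743 genes were tested and 625 rose and 918 fell. There the medians of matrix proteases (−0.20), growth factors (−0.52, adjusted p = 0.0146), cell cycle genes (−0.25) and modulated smooth muscle genes (−0.079) reversed. With an estimated correlation camera called 0 of 28 lists, against 18 with the preset value and 12 by fry. With DESeq2 the test direction reversed for BMP targets (median 0.0047) and proteases (0.10), neither called. Uncalled genes near 0 reversed for Ddx3y with library totals (0.018) and equal cell numbers (0.00995), Tgfbr2 with the stricter cell filter (0.011) and Eif2s3y after thinning (−0.011).

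Leaving out each library gave 779 (without WT 1) to 1128 higher and 1035 (without WT 1) to 1286 lower genes, 17 to 19 lists, 217 to 368 genes for the subcluster with the highest Rgs5, −6750 to −6550 CPM for the matrix score and 0.0852% to 0.118% for the endothelial-like share. Fewer libraries in the fit lower its power. Ranges for uncalled genes crossed 0: Tgfbr2 −0.14 to 0.052, Xist −0.070 to 0.38, Ddx3y −0.084 to 0.065 and Eif2s3y −0.035 to 0.052. Uncalled lists whose test turned had medians of −0.22 to −0.10 (TGF-beta ligands), −0.15 to 0.19 (BMP targets), −0.38 to 0.47 (cell cycle) and 0.012 to 0.12 (glycolysis).

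The interaction of the 2 largest subclusters gave 1 gene without KO 1, 16 without WT 2 and 19 at resolution 0.8. Without centring per library other subclusters were compared, and Nupr1 (0.095), Olfr655 (0.92) and Col3a1 (0.075) reversed. The TGF-beta target list gave a score difference of −3800 CPM in place of the matrix lists. The endothelial-like share was 0 at resolution 0.3 and 0 with the stricter cell filter (exact p = 1 in both). The cause was not tested for any of these changes, apart from fewer genes or libraries where an alternative removes them. Depth limits genes with few UMIs, and 2 libraries per genotype limit all tests over single values.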

Other observations

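The comparison of the subcluster with the highest Rgs5 and the description of cells with interferon-induced UMIs were chosen only after the result was seen.

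A subcluster of 1103 smooth muscle cells stood out by Rgs5 (1766 CPM), with Adamtsl1, Prrx2, Dlx6, Fbln1 and Sfrp2 among its leading genes. It held 4.49% and 8.36% of WT 1 and WT 2 and 5.27% and 14.1% of KO 1 and KO 2 cells, shares that overlapped between genotypes. When genes that differ between genotypes were kept in the clustering, most cells of the clusters led by Rgs5 or Adamtsl1 were split by genotype, with 104 and 298 WT against 5 and 7 KO cells in one and 1 and 1 WT against 236 and 562 KO cells in the other. Several genotype effects were smaller or opposite there by an edgeR interaction term, which called 134 genes with a higher and 154 with a lower log2 change than in the other tested subclusters, from 217 without KO 2 to 368 without WT 1. Gja1, the gap junction protein connexin 43, stood at 101 and 103 CPM in WT and 174 and 218 CPM in KO in the other subclusters, and at 141 and 105 CPM in WT and 76.9 and 91.7 CPM in KO in this one (difference −1.44, SE 0.12). The chemokine Cxcl12 went from 32.3 and 34.3 to 77.4 and 72.6 CPM elsewhere and stood at 186 and 144 CPM in WT and 188 and 177 CPM in KO here (−0.98, SE 0.11). Sfrp2, a Wnt modulator, stood at 1279 and 1557 CPM in WT and 907 and 832 CPM in KO here, against 160 and 192 and 195 and 180 CPM elsewhere. Differences for Pmepa1 and Nupr1 were 0.89 and 0.97, with KO levels of 244 and 207 CPM and 133 and 123 CPM here. The 10 genes with the smallest p, also F2r, Piezo2, Ecm2, Pcsk5 and Ablim1, kept their call and direction without each library in turn.

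Cells with at least 5 UMIs of Isg15, Ifit1, Ifit3, Ifit3b and Rsad2 numbered 154 in KO 1 and 27 in KO 2 against 3 in WT 1 and 2 in WT 2. The KO libraries differed from each other in this share by more than the lower of them differed from either WT library. UMIs of eGFP were found in 99.8% of the cells of each library. Of the transcripts of the 8 endothelial-like cells, all from KO libraries, 133 CPM were eGFP. The largest KO cluster held 8103 CPM and the largest WT cluster 5829 CPM.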
